A study of Mus musculus with 7 samples.

How the data were processed

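Total RNA from whole adrenal glands of 7 female mice aged 2 months was measured on 1-colour Affymetrix whole-transcript arrays, with 3 wild-type (WT) littermates and 4 mice carrying sf1:Cre and 2 floxed Ezh2 alleles (KO). The design text says that the glands came from 4 KO and 3 WT mice, and the labels call the arrays biological replicates and describe an uncontrolled mixed background of mainly C57BL/6 and SV129. Biotinylated cDNA was made with the GeneChip WT PLUS kit, per the labels' protocols.

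The deposited value table holds log2 expression values for 41345 probe sets on the 7 arrays, made by the authors with RMA, per the submitters' processing notes. RMA is a method that corrects background, normalizes arrays by quantiles and summarises probes on a log2 scale. The RMA version and the genome build behind the probe sets are not given in the sources used here. The array medians lay between 5.32 and 5.38 over all probe sets. These close medians do not settle the scale, since centring the arrays on their medians changed the balance of rises and falls, as given below. RMA values of weakly expressed genes lie close to a floor, and folds of genes near it are compressed. No detection calls or probe-level signals were used here, so no level could be set against background. A second deposited table holds the authors' own comparison of KO with WT as a log2 fold change, a p-value and an adjusted p-value for 28638 gene symbols. The test behind the authors' p-values is not given in the sources used here, and this table was used only for comparison and for genes that could not be named from the value table, some of which are not reported here.

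Probe sets were named through the platform's annotation. Exactly 1 gene symbol was given for 23521 probe sets, several symbols for 1820, and 16004 are unnamed here. Entrez identifiers of 23328 of the named probe sets matched the gene annotation of the mouse reference assembly GRCm38.p6, and 0 symbols changed. No coordinates were taken from that table, which served for names and for the order of neighbouring genes. Probe sets with several symbols were left out of the named genes. For the 1082 genes with more than 1 probe set, the one with the highest mean over all 7 arrays was used, which left 22180 genes, with no filter on low values. The same value was given on all 3 WT arrays for 711 genes, Ezh2 among them, and 0 of the genes called below were of this kind.

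KO was compared with WT with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (with statmod 1.5.0), without covariates. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower. Changes are given as log2 KO minus WT with the standard error (SE) of limma, and group values as mean ± SD. Every adjusted p of a gene is from limma, two-sided. The median residual SD over genes was 0.0972 and the median SE of a change was 0.0703 on the log2 scale. The number of arrays limits the precision, since the fit leaves 5 residual degrees of freedom.

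Before the data were examined, 27 gene lists were fixed (pathways, adrenal zones, other cell types, Polycomb targets and signs of handling). The 26 lists with at least 3 measured members were tested with camera of limma at an inter-gene correlation of 0.01, two-sided and adjusted over the 26 lists. The test was repeated with a correlation estimated for each list. The lists were also tested with fry, which asks whether a list's genes move, on balance, one way, whereas camera compares them with the other genes. Ranges of a list's adjusted p over its alternatives include fry. Counts of called list members are adjusted over all genes tested unless they are said to be adjusted over the list alone. The genes named in the text were also set by a rule fixed before the data were examined. They are Ezh2, the 12 largest rises and 12 largest falls among called genes whose KO and WT arrays do not overlap, and any member of a list. Predicted, RIKEN, olfactory receptor, microRNA and small nucleolar genes and accession-like symbols were left out of the rises and falls. Any other gene named is said to have been chosen after its values were seen.

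The fit was tested on simulated data for this comparison, with 200 of the 22180 genes changed in each of 10 draws. It recovered 91.7% of genes changed by 1 log2 unit and 63.3% of those changed by 0.5, and 5.25% of its calls were false. A simulated shifted list, that of chromaffin cells, was called in 10 of 10 draws. The noise was drawn independently for each gene, whereas the estimated correlation within that list was 0.30 in the real data. The simulated rates are therefore not error rates of the real comparison. Alternatives covered a filter on low values, the treatment of several probe sets, the variance prior, the normalization between arrays, array weights, the replicate number as a block, the chromaffin list mean as a covariate, a fold minimum, the list tests, and leaving out each array in turn. The adipocyte list mean as a covariate was added after the data were seen.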

Results

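Gene expression was measured in whole adrenal glands of female mice aged 2 months by 1-colour microarray. There were 4 mice with Ezh2 deleted through sf1:Cre (KO), a Cre recombinase placed under the control of the gene for steroidogenic factor 1 (Nr5a1), which is active in cells of the adrenal cortex. The 3 wild-type (WT) mice were littermates. Ezh2 is the histone H3 lysine 27 methyltransferase of Polycomb repressive complex 2 (PRC2), so the comparison addresses which transcripts differ in the gland when this enzyme is deleted in steroidogenic cells. The whole gland was used, so each array also holds RNA of medullary chromaffin cells, capsule, vessels, immune cells and any adhering fat. The deposited values were RMA log2 values of 41345 probe sets per array, from which 22180 genes were tested.

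In KO glands the largest rises were those of Ibsp, Ptprq and Nrn1, and the largest falls those of Hamp, Akr1d1 and Akr1c18. The markers of the X-zone, the inner cortical zone of the mouse adrenal, fell, and most markers of chromaffin cells rose. Of 14 gonadal markers, 4 rose, Inha, Gata4 and Wt1 among them. Of 15 genes of steroid synthesis 13 did not pass the test, although 9 of the 15 had an unadjusted p under 0.05. With limma, 1928 of 22180 genes were called, 1140 higher and 788 lower in KO. Of these, 566 rose and 236 fell by at least 1.5-fold, and 725 of the 1928 had an adjusted p under 0.01. When each array was centred on its median, 1005 genes were higher and 1329 lower, so that 43.1% of calls were rises in place of 59.1%. The KO and WT arrays did not overlap for 20.2% of all genes, where chance gives 5.71%, and for each of the 1928 called genes. The first principal component held 56.7% of the variance and separated the groups. Pearson's r across genes was 0.993 to 0.996 between arrays of a group and 0.984 to 0.990 between arrays of different groups. The counts fell by more than 1.5 times without WT replicate 2 (633 higher, 394 lower) and without WT replicate 3 (594 higher, 322 lower). The count of lower genes also fell by more than that without KO replicate 2 (477) and without KO replicate 3 (515).

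Ezh2 itself was at 7.08 on each of the 3 WT arrays and at 7.04 ± 0.13 in KO (SD, n = 4), a log2 change of -0.04 (SE 0.07, 95% interval -0.20 to 0.13, adjusted p = 0.816). The KO arrays lay at 6.86, 7.04, 7.10 and 7.15. Which exons its single probe set covers and which were deleted are not given in the sources used here, and the gland also holds cells outside the Cre domain, so this value does not check the labels. In the authors' deposited table the log2 change of Ezh2 was -0.08 with an adjusted p of 0.725. None of the 11 measured PRC2 components was called by limma, also when adjusted over the list alone, and 1 had an unadjusted p under 0.05. There were log2 changes of -0.23 for Jarid2 (adjusted p = 0.103), -0.15 for Eed (adjusted p = 0.231), -0.08 for Suz12 and -0.05 for Ezh1. The list as a whole was not called by camera (adjusted p = 0.159).

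The 12 genes with the largest rises ranged from 16.4-fold to 3.31-fold. Ibsp, a sialoprotein of mineralized bone matrix, was at 4.97 ± 0.15 in WT (SD, n = 3) and 9.01 ± 0.44 in KO (SD, n = 4), a log2 change of 4.04 (SE 0.23, adjusted p = 0.000407). Ptprq, a receptor-type phosphatase of sensory hair cells, rose by 3.46 log2 units (adjusted p = 0.00113), and Nrn1, neuritin, a membrane-anchored protein of neurons, rose 9.08-fold (adjusted p = 0.000114). Rhcg, an ammonium transporter, rose 5.71-fold from 5.04 ± 0.16 to 7.55 ± 0.21. Inha, the inhibin alpha subunit, rose 5.26-fold from 6.56 ± 0.39 to 8.96 ± 0.24 (adjusted p = 0.00161). The chemokine receptor Cxcr4 rose 4.41-fold (adjusted p = 0.000218), the engulfment receptor Megf10 4.39-fold, the neuronal glycine transporter Slc6a5 4.08-fold, the matrix metalloproteinase Mmp2 3.42-fold and the transmembrane protein Tmem130 3.31-fold. The ganglioside sialyltransferase St8sia5 rose 4.34-fold on the brighter of its probe sets, whereas its second probe set gave a log2 change of -0.003 (adjusted p = 0.972) and the mean of both one of 1.06. Chil3, a chitinase-like protein of macrophages, rose 4.93-fold (adjusted p = 0.0113) and had an adjusted p of 0.0706 with the adipocyte list mean as a covariate, chosen after the data were seen (range over 17 alternatives 0.00562 to 0.960). In WT, 5 of these genes (Ibsp, Ptprq, Rhcg, Chil3 and St8sia5) lay between percentiles 32.5 and 37.0 of gene levels.

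Hamp, which encodes the iron-regulating hormone hepcidin, had the largest change of all called genes. It was at 10.5 ± 0.33 in WT (SD, n = 3) and 3.01 ± 0.42 in KO (SD, n = 4), a log2 change of -7.48 (SE 0.25, adjusted p = 7.3e-05) or 179-fold, and its KO level was at percentile 5.41 of gene levels. Its neighbour Hamp2, chosen after its values were seen, was at 4.00 ± 0.09 and 3.78 ± 0.14 (log2 change -0.22, adjusted p = 0.179). Akr1d1, the steroid 5-beta-reductase, fell 31.9-fold from 12.1 ± 0.06 to 7.08 ± 1.20 (adjusted p = 0.00394). Akr1c18, the progesterone-inactivating 20-alpha-hydroxysteroid dehydrogenase, fell 16.7-fold from 12.9 ± 0.07 to 8.85 ± 1.01 (adjusted p = 0.00427). The cytochrome P450 gene Cyp2f2 fell 16.0-fold (adjusted p = 0.000451), and its second probe set gave a log2 change of -1.60 (adjusted p = 0.00882). Falls were 14.0-fold for Fetub (fetuin B), 11.2-fold for Vnn3 (a vanin), 9.55-fold for the odorant-binding protein Obp2a and 7.98-fold for the serine protease inhibitor Serpinb1a. The lipid-antigen presenting molecule Cd1d1 fell 7.61-fold, from 9.81 ± 0.06 to 6.88 ± 0.15, with the smallest adjusted p of these genes (5.3e-05). Fa2h, the fatty acid 2-hydroxylase, fell 7.06-fold, Nrep 6.97-fold and the acid phosphatase Acpp 5.86-fold. The WT arrays spread widely for Obp2a, Fa2h and Acpp, with SDs of 0.93, 0.82 and 0.67 (n = 3). The log2 change of Obp2a was -2.73 without WT replicate 3 and -3.61 without WT replicate 2. Without any single array, each of the 24 genes of these 2 groups was still called, with a highest adjusted p of 0.0458, that of Chil3.

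**Figure D1:**
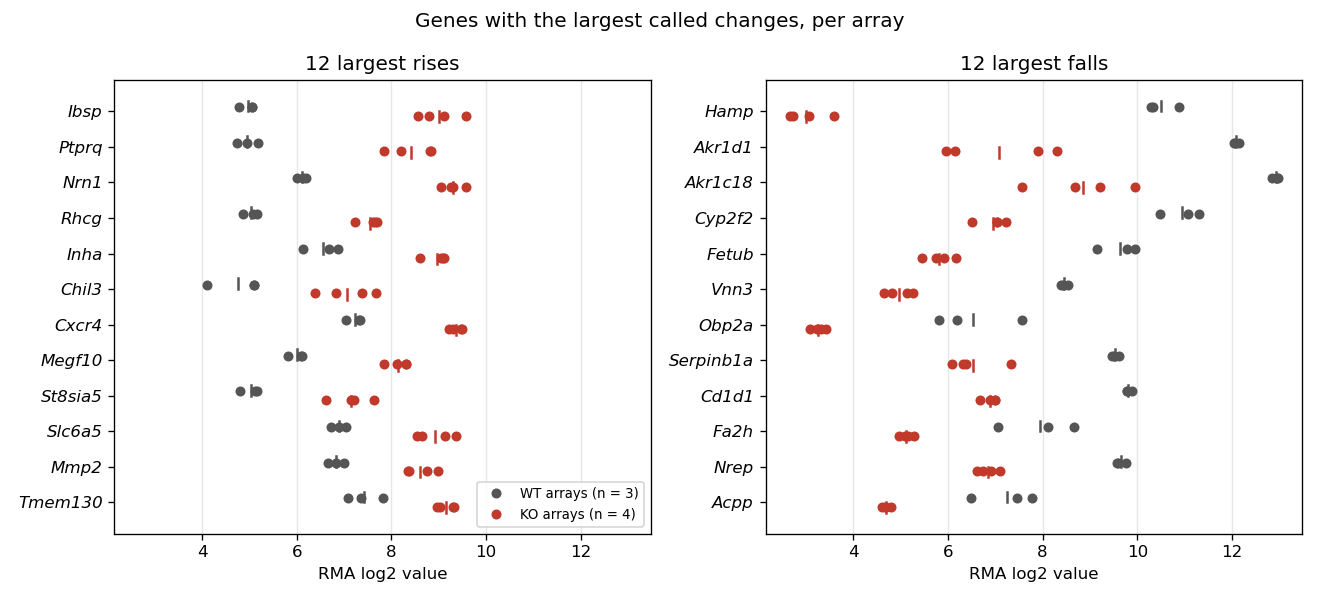
RMA log2 values (x axis) of the 12 genes with the largest called rises and the 12 with the largest called falls (y axis), with each WT array (n = 3) and each KO array (n = 4) as a point and group means as vertical ticks. The 24 genes were chosen among those whose KO and WT points do not overlap, and Hamp falls from a mean of 10.5 to 3.01.

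The 4 markers of the X-zone, a transient inner cortical zone found in young mice, were all lower in KO. Akr1c18 and Cyp2f2 fell as given above, Thrb, a thyroid hormone receptor, fell from 9.07 ± 0.09 (SD, n = 3) to 8.05 ± 0.25 (SD, n = 4; log2 change -1.02, SE 0.13, adjusted p = 0.00508), and the phosphoinositide kinase gene Pik3c2g had a log2 change of -0.62 (SE 0.14, adjusted p = 0.0390). The same 4 of 4 were called when adjusted over the list alone. The median log2 change of the list was -2.51 (camera adjusted p = 2.4e-05, adjusted p = 0.131 with an estimated correlation), and the list was called in each of the 7 fits that left out 1 array. Its median was -4.00 when genes of below-median level were left out and -1.60 when each probe set was tested on its own. Over its 19 alternatives the adjusted p was 2.0e-06 to 0.508. The probe set of Pik3c2g was at low levels in both groups, 4.30 in WT and 3.68 in KO.

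Transcripts of steroid synthesis stayed at high levels in both groups. Of 15 measured genes of steroid synthesis and ACTH reception, 1 rose and 1 fell, and 3 rose and 3 fell when adjusted over the list alone. By limma 9 of the 15 had an unadjusted p under 0.05, against 5063 of all 22180 genes. The lipoprotein receptor Scarb1 rose by 0.34 (SE 0.08, adjusted p = 0.0390), and Nr0b1 (Dax1), a nuclear receptor that represses steroidogenic factor 1 targets, fell by 1.13 (SE 0.21, adjusted p = 0.0187). Star, the cholesterol carrier of mitochondria, was at 13.1 ± 0.04 in WT (SD, n = 3) and 12.9 ± 0.06 in KO (SD, n = 4; adjusted p = 0.105). Cyp11a1, the side-chain cleavage enzyme, had a log2 change of 0.17 (adjusted p = 0.189), Cyp11b1 one of -0.05 (adjusted p = 0.563) and Nr5a1 one of 0.44 (adjusted p = 0.170). The list was not called by camera (median -0.05, adjusted p = 0.680), and its median was 0.02 after a further quantile normalization, -0.10 with arrays centred on their medians and -0.03 without WT replicate 2. Among zona glomerulosa markers, 1 of 13 rose, the potassium channel Kcnk9 (log2 change 0.64, adjusted p = 0.00966), also when adjusted over the list alone. The aldosterone synthase Cyp11b2 had a log2 change of 0.29 (adjusted p = 0.321). The glomerulosa list had a median of 0.13 and a mean of -0.02 (camera adjusted p = 0.167), and was called without KO replicate 1 (median 0.22, adjusted p = 0.0316, range over 19 alternatives 0.000669 to 0.610). Its median was 0.06 without WT replicate 2, 0.07 without KO replicate 4 and 0.08 with arrays centred on their medians. Of 7 zona fasciculata markers Scarb1 alone was called, with 2 higher and 3 lower when adjusted over the list alone (median -0.05, with the same 3 other values as the steroid list, camera adjusted p = 0.552). Of these 7 markers 6 are also in another list, as are 8 of the 15 steroid genes. Scarb1 is in both, so the 2 lists are not independent results. Akr1b7, a fasciculata gene not named by a probe set here, had a log2 change of 0.44 in the authors' deposited table (adjusted p = 0.0337).

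Genes of cholesterol synthesis and uptake were lower as a list in KO. Of 20 measured members, 5 fell and 0 rose, with the same counts when adjusted over the list alone. Hmgcs1, which makes HMG-CoA, fell from 10.7 ± 0.11 (SD, n = 3) to 9.52 ± 0.27 (SD, n = 4), a log2 change of -1.17 (SE 0.14, adjusted p = 0.00427). Fdps, which makes farnesyl diphosphate, fell by 0.93 (adjusted p = 0.0337), the sterol carrier Stard4 by 0.70, the sterol isomerase Ebp by 0.69 and the sterol reductase Tm7sf2 by 0.40. The median log2 change was -0.36 (camera adjusted p = 2.7e-05), with an adjusted p of 0.408 with an estimated correlation and of 0.0853 by fry, a test without reference to other genes (range over 19 alternatives 5.2e-06 to 0.408). The list mean was 7.84 on KO replicate 4 and between 8.22 and 8.33 on the other KO arrays, and without KO replicate 4 the median was -0.23 (adjusted p = 0.000303). On the same arrays the chromaffin list mean was 0.85 higher in KO and the adipocyte list had a mean log2 change of -1.02. Sqle, Insig1 and Cyp51 had log2 changes of -0.42, -0.68 and -0.63 with adjusted p values of 0.374, 0.143 and 0.167.

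Markers of the capsule and stroma rose as a list. Of 16 measured, 6 rose and 1 fell, and 7 rose and 1 fell when adjusted over the list alone. Lum, a proteoglycan of collagen fibres, rose from 6.88 ± 0.09 (SD, n = 3) to 8.37 ± 0.33 (SD, n = 4; SE of the change 0.17, adjusted p = 0.00344). Tcf21, a transcription factor of capsular and stromal progenitors, rose by 1.48 (SE 0.11, adjusted p = 0.00106), the growth factor receptor Pdgfra by 1.25, Gli1 by 0.82, Col1a2 by 0.74 and Thy1 by 0.68, while Nr2f1 fell by 0.38. The median log2 change was 0.43 (camera adjusted p = 2.7e-05, adjusted p = 0.307 with an estimated correlation), or 0.71 with the adipocyte list mean as a covariate, chosen after the data were seen. Of 11 genes of the hedgehog pathway, which signals from cortex to capsule, 6 rose and 0 fell, and 6 rose and 1 fell when adjusted over the list alone. Besides Gli1 these were the inhibitor Hhip (0.86, SE 0.13, adjusted p = 0.00933), the receptor Ptch1 (0.79, adjusted p = 0.0194), Gli2 (0.60), Cdon (0.59) and Sufu (0.25). The ligand Shh had a log2 change of 0.09 (adjusted p = 0.517). The hedgehog list had a median of 0.25, or 0.14 with the mean of a gene's probe sets (camera adjusted p = 0.00198, adjusted p = 0.307 with an estimated correlation). Gli1 is a member of both lists. On the same arrays the mean of the chromaffin list was 9.58 ± 0.05 in WT and 10.4 ± 0.09 in KO.

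Of 14 measured markers of gonadal cells and of the adrenogonadal primordium, 4 rose and 0 fell, and 5 rose when adjusted over the list alone. Inha rose as given above. Gata4, a transcription factor of gonadal somatic cells, rose from 6.50 ± 0.28 (SD, n = 3) to 7.47 ± 0.18 (SD, n = 4; log2 change 0.97, SE 0.15, adjusted p = 0.00941). Wt1, which acts in the primordium that gives rise to adrenal and gonad, rose by 0.96 (SE 0.10, adjusted p = 0.00257), and Amhr2, the receptor of anti-Müllerian hormone, by 0.52 (adjusted p = 0.0210). Foxl2, a transcription factor of granulosa cells, had a log2 change of 0.64 (adjusted p = 0.0589), and Cyp17a1 one of 0.10 (adjusted p = 0.685). The gonadal list had a median of 0.09 (camera adjusted p = 0.00198, adjusted p = 0.254 with an estimated correlation). The median was 0.06 without WT replicate 2, 0.14 without KO replicate 2, 0.04 with arrays centred on their medians, 0.06 after a further quantile normalization, 0.05 with the adipocyte list mean as a covariate and 0.96 when genes of below-median level were left out. On the same arrays the chromaffin list mean was 0.85 and the capsule and stroma list mean 0.55 higher in KO. In the authors' deposited table the gonadotropin receptor Lhcgr had a log2 change of 0.75 (adjusted p = 0.0601).

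Among 49 measured developmental transcription factors, a family rich in PRC2 targets, 7 rose and 1 fell, and 8 rose and 1 fell when adjusted over the list alone. Besides Gata4 and Wt1 the rises were those of Tbx15 (1.07, SE 0.14, adjusted p = 0.00481), Hand2 (1.00, SE 0.12, adjusted p = 0.00352), Isl1 (0.90), Tbx18 (0.48) and Tbx2 (0.24), and Meis2 fell by 0.33. Hand2 and Isl1 are known to act in sympathoadrenal cells, and the chromaffin list mean was 0.85 higher in KO on these arrays. The list's median was 0.06, or 0.02 without WT replicate 2, 0.004 with arrays centred on their medians, 0.01 after a further quantile normalization and 0.09 when genes of below-median level were left out (camera adjusted p = 0.0105, adjusted p = 0.322 with an estimated correlation). Its call was lost after a further quantile normalization (adjusted p = 0.0857) and with the adipocyte list mean as a covariate (adjusted p = 0.0740), and over its 19 alternatives the adjusted p was 0.00310 to 0.785. Of 36 Hox genes, 1 rose and 4 fell, and 2 rose and 6 fell when adjusted over the list alone. Hoxc4 rose by 0.49, and Hoxb6 (-0.72, SE 0.11, adjusted p = 0.0102), Hoxb5 (-0.56), Hoxb9 (-0.47) and Hoxb8 (-0.27) fell. The list had a median of -0.02, or 0.004 without KO replicate 1, 0.02 with the adipocyte list mean as a covariate, -0.07 with arrays centred on their medians and -0.03 after a further quantile normalization, and was not called (camera adjusted p = 0.350), but was called when genes of below-median level were left out (median -0.17, adjusted p = 0.0167, range over 19 alternatives 0.0167 to 0.961).

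Of 7 inhibitors of cyclin-dependent kinases, 4 rose and 1 fell, and 4 rose and 2 fell when adjusted over the list alone. Cdkn1c rose from 8.29 ± 0.17 (SD, n = 3) to 9.20 ± 0.26 (SD, n = 4; log2 change 0.92, SE 0.15, adjusted p = 0.0130). Cdkn1a rose by 0.55, Cdkn2a, at a locus that PRC2 is known to silence, by 0.35 (SE 0.08, adjusted p = 0.0371) and Cdkn2b by 0.20, while Cdkn1b fell by 0.42. The list was not called by camera (adjusted p = 0.125) and was called by fry, which asks a different question and does not compare the list with other genes (adjusted p = 0.0185, range over 19 alternatives 0.0185 to 0.747). Of 26 proliferation genes 1 fell, the ribonucleotide reductase subunit Rrm2 (-0.47, SE 0.07, adjusted p = 0.00695), also when adjusted over the list alone. Mki67 and Top2a each had a log2 change of -0.27 (adjusted p = 0.321 and 0.309). The proliferation list had a median of -0.13, or -0.26 when genes of below-median level were left out (camera adjusted p = 0.00233), with an adjusted p of 0.307 with an estimated correlation and of 0.0505 with the adipocyte list mean as a covariate (range over 19 alternatives 0.000361 to 0.307). On the same arrays the mean log2 change was 0.85 for chromaffin, 0.55 for capsule and stroma and -2.43 for X-zone markers.

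In the cyclic AMP pathway, through which ACTH acts, single genes changed in both directions. Of 16 phosphodiesterases, which degrade cyclic nucleotides, 3 rose and 1 fell, with the same counts when adjusted over the list alone. Pde7b rose from 7.29 ± 0.28 (SD, n = 3) to 8.49 ± 0.31 (SD, n = 4; log2 change 1.19, SE 0.19, adjusted p = 0.0118), Pde3a rose by 0.71 (SE 0.07, adjusted p = 0.00197) and Pde1b by 0.34. Pde8b, a cyclic AMP phosphodiesterase of steroidogenic cells, fell by 0.59 (SE 0.14, adjusted p = 0.0418). The list's median was 0.04. It was 0.08 without WT replicate 2 or KO replicate 1, 0.03 without WT replicate 3 and 0.02 without KO replicate 4. It was -0.02 when genes of below-median level were left out, -0.01 with arrays centred on their medians, 0.03 after a further quantile normalization and 0.09 with the adipocyte list mean as a covariate. The phosphodiesterase list was not called by camera (adjusted p = 0.159) and was called by fry (adjusted p = 0.0376, range over 19 alternatives 0.0376 to 0.568). Of 17 adenylyl cyclase and protein kinase A genes, 4 rose and 1 fell, and 7 rose and 2 fell when adjusted over the list alone. Adcy7 rose by 0.69 (SE 0.12, adjusted p = 0.0157), Prkar1b by 0.47, Gnas by 0.39 and Adcy6 by 0.32, and Adcy9 fell by 0.48 (adjusted p = 0.00508). The list had a median of 0.18 and was not called (camera adjusted p = 0.104), although it was called by fry (adjusted p = 0.0175), without KO replicate 1 (adjusted p = 0.0410), with arrays centred on their medians (adjusted p = 0.0465) and after a further quantile normalization (adjusted p = 0.0457, range over 19 alternatives 0.0175 to 0.361). It was also called with the adipocyte list mean as a covariate (adjusted p = 0.0312), and its median was 0.11 without KO replicate 3 (adjusted p = 0.112). The chromaffin list mean was 0.85 higher on the same KO arrays. Of 12 canonical Wnt targets, Lgr5 rose by 0.93 (SE 0.12, adjusted p = 0.00536) and Tnfrsf19 fell by 0.45, while Axin2 had a log2 change of 0.18 (adjusted p = 0.311). When adjusted over the list alone, 3 rose and 2 fell (camera adjusted p = 0.363).

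Markers of the chromaffin cells of the medulla, which lie outside the sf1:Cre domain, rose. Of 12 measured, 10 rose and 0 fell, and 11 rose when adjusted over the list alone. Pnmt, which makes adrenaline, rose from 8.65 ± 0.23 (SD, n = 3) to 9.92 ± 0.24 (SD, n = 4; log2 change 1.27, SE 0.15, adjusted p = 0.00427). Ddc rose by 1.14 (SE 0.08, adjusted p = 0.000756), Npy by 0.98, Dbh by 0.97, Th, the rate-limiting enzyme of catecholamine synthesis, by 0.96 (SE 0.08, adjusted p = 0.00137) and chromogranin A (Chga) by 0.62. The log2 changes of Cartpt and Gch1 were 0.92 (adjusted p = 0.0505) and 0.16 (adjusted p = 0.313). The list's median was 0.96 (camera adjusted p = 5.1e-14, adjusted p = 0.131 with an estimated correlation). The list mean lay between 9.54 and 9.63 on the WT arrays and between 10.3 and 10.5 on the KO arrays. Of 7 Schwann and glial markers, Cdh19 rose by 0.74 (SE 0.14, adjusted p = 0.0195), and 2 rose when adjusted over the list alone. That list's call (median 0.13, camera adjusted p = 0.0495, adjusted p = 0.307 with an estimated correlation) was kept in 3 of the 7 fits that left out 1 array, with an adjusted p of 0.139 without WT replicate 1, 0.0663 without WT replicate 2, 0.0588 (median 0.07) without KO replicate 2 and 0.0920 without KO replicate 4 (range over 18 alternatives 0.0185 to 0.747). It was also lost after a further quantile normalization (adjusted p = 0.147), with a trended and robust variance prior (0.0513) and with each probe set tested on its own (0.0502).

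The endothelial and macrophage lists had medians below 0. Of 11 endothelial markers, Tek fell by 0.47 (SE 0.11, adjusted p = 0.0390) and Plvap by 0.42 (SE 0.10, adjusted p = 0.0464), and 3 fell when adjusted over the list alone (median -0.09, camera adjusted p = 0.122). The endothelial list was called without WT replicate 2 (median -0.13, adjusted p = 0.0338) and without KO replicate 3 (adjusted p = 0.0480), and its median was -0.05 without WT replicate 3 and -0.14 with arrays centred on their medians (range of adjusted p over 19 alternatives 0.000417 to 0.609). The lowest, 0.000417 by camera, was with the chromaffin list mean as a covariate, where the list was called higher (median 0.82). Of 14 macrophage markers, lysozyme (Lyz2) fell by 0.71 (SE 0.09, adjusted p = 0.00427) and Trem2 rose by 0.62 (SE 0.13, adjusted p = 0.0277), and 1 rose and 2 fell when adjusted over the list alone. The macrophage list's call (median -0.20, camera adjusted p = 0.0452, adjusted p = 0.547 with an estimated correlation) was kept in 3 of the 7 fits that left out 1 array. Its adjusted p was 0.0663 without WT replicate 2, 0.0699 without WT replicate 3, 0.0988 (median -0.12) without KO replicate 2 and 0.1001 without KO replicate 4 (range over 19 alternatives 0.00992 to 0.747). It was also lost when genes of below-median level were left out (adjusted p = 0.127), with arrays centred on their medians (0.121) and by fry (0.196). None of 6 antigen presentation genes, 10 lymphocyte genes or 5 kidney genes was called by limma, also when adjusted over the list alone (camera adjusted p = 0.156, 0.159 and 0.648). The antigen presentation list was called without WT replicate 1 (adjusted p = 0.0355, range over 19 alternatives 0.0355 to 0.747), and 1 gene of each list had an unadjusted p under 0.05. The only red blood cell gene measured, Slc4a1, had a log2 change of -0.08 (adjusted p = 0.545).

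None of 10 adipocyte markers was called by limma, also when adjusted over the list alone, although 2 had an unadjusted p under 0.05 and all 10 lay below 0, with a median of -0.83. Fat markers varied between arrays of a group. The list mean was 8.53, 9.77 and 9.48 on the WT arrays and 7.02, 9.05, 8.82 and 8.06 on the KO arrays. Ucp1, the uncoupling protein of brown fat, had a log2 change of -2.88 (SE 0.79, adjusted p = 0.0744) and Cidea one of -1.97 (adjusted p = 0.112). The list's call (camera adjusted p = 0.0263, adjusted p = 0.550 with an estimated correlation) was lost without KO replicate 1 (adjusted p = 0.154, median -0.32), WT replicate 2 (0.143), WT replicate 3 (0.0671) or KO replicate 4 (0.0628), with arrays centred on their medians (0.132), when genes of below-median level were left out (0.147) and by fry (0.274), and over its 19 alternatives the adjusted p was 0.00158 to 0.747. With the adipocyte list mean as a covariate, chosen after the data were seen, 583 genes were higher and 364 lower in KO.

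Immediate early genes, which respond to stimulation and to handling of tissue, were higher as a list. Of 10 measured, Egr1 rose from 7.11 ± 0.38 (SD, n = 3) to 8.53 ± 0.20 (SD, n = 4; log2 change 1.42, SE 0.19, adjusted p = 0.00535) and Fos rose by 1.22 (SE 0.21, adjusted p = 0.0146), and 7 rose when adjusted over the list alone. Nr4a1, Fosb and Jun had log2 changes of 1.19, 0.71 and 0.10, with adjusted p values of 0.0736, 0.121 and 0.669. The list's median was 0.52 (camera adjusted p = 0.000422, adjusted p = 0.307 with an estimated correlation), and the chromaffin list mean was 0.85 higher on the same KO arrays. Of the 3 measured neighbours of Nr5a1, whose regulatory sequence drives the Cre transgene, Nr6a1 rose by 0.65 (SE 0.05, adjusted p = 0.00147), and 2 rose when adjusted over the list alone. Psmb7 had a log2 change of 0.21 (adjusted p = 0.0592) and Nek6 one of 0.09 (camera adjusted p of the list 0.00625, adjusted p = 0.307 with an estimated correlation).

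Of the 26 lists tested, camera called 13, with 8 higher and 5 lower. With estimated correlations camera called 0 lists, of which 3 (X-zone, chromaffin and gonadal) had an unadjusted p under 0.05. The 13 lists that fry, with its different question, called leave out the cholesterol, macrophage and adipocyte lists and hold the phosphodiesterase, adenylyl cyclase and CDK inhibitor lists in their place. Other splits of the arrays into 3 and 4 gave a median of 4 lists called at the preset correlation, and the most, 12, came from splits of 3 KO arrays against the 3 WT arrays and 1 KO array.

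**Figure D2:**
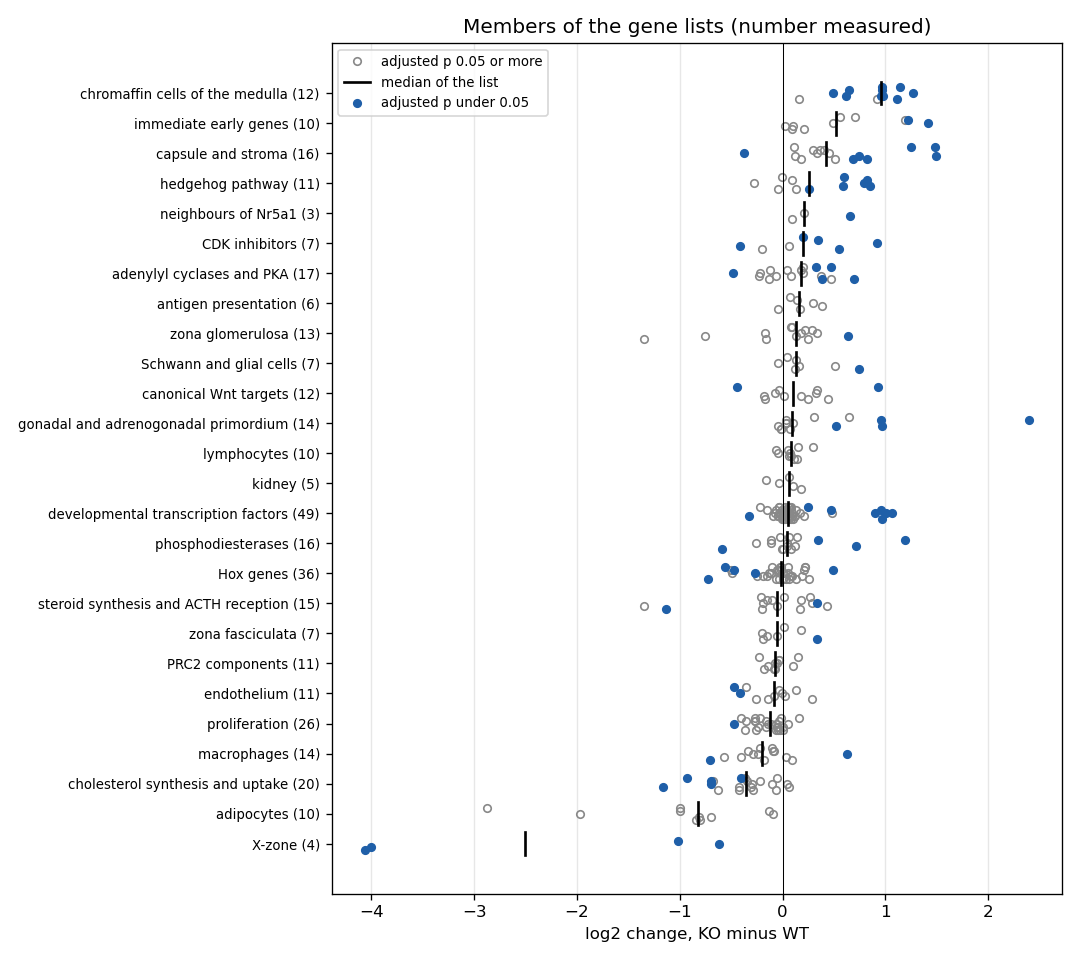
Log2 change, KO minus WT (x axis), of each measured member of the 26 tested gene lists (y axis, number measured in brackets), with members called by limma filled, others open, and the list's median as a black bar. X-zone markers lie lowest, with a median of -2.51, and chromaffin markers highest, with a median of 0.96.

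The changes were set against the authors' deposited table, where 1594 genes were higher and 1191 lower at an adjusted p under 0.05. Over the 19252 genes in both, the log2 changes had a Pearson's r of 0.984 across genes, which are not independent replicates. Of 1758 called genes in both, 1757 had the same sign and 1661 also had an adjusted p under 0.05 in that table. In the other direction, 2280 of the genes in both had an adjusted p under 0.05 in that table, and 1661 of these were called here. That table is the authors' comparison of the same KO and WT groups, so the match is no independent result. Hamp had a log2 change of -7.46 and Ibsp one of 4.04 in the authors' deposited table.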

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

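The tests of the chromaffin pattern, and those of dilution and of fewer cells for the X-zone pattern, were chosen after the results were seen. The split counts and the tests of genes near Ezh2 were fixed before.

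In the KO group, single arrays stood far from the others for 3 of 52 genes and list means examined, where chance alone gives about 2.6. The mean of the adenylyl cyclase and protein kinase A list was 7.51 on KO replicate 3 and 7.46 on the other 3 KO arrays, a gap of 0.957 of the group's range. Inha was 8.60 on KO replicate 4 and between 9.06 and 9.11 on the others (0.889 of the range), and Rhcg was 7.23 on KO replicate 4 and between 7.62 and 7.69 on the others (0.847 of the range). Among the 16004 probe sets unnamed here, which no comparison used, limma called 44, of which 20 were higher and 24 lower in KO.

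All 12 measured chromaffin markers lay above 0, and the list mean rose by 0.85 (95% interval 0.71 to 1.00, two-sided exact permutation p = 0.0286, the smallest that 3 against 4 arrays can give). None of these 12 genes is in another list, and Chga, Chgb and Scg2, which encode proteins of secretory granules, rose by 0.62, 0.49 and 0.64. A lower share of cortex would by itself raise every other cell type alike. An equal rise is argued against, because chromaffin minus endothelium differed by 0.97 (95% interval 0.64 to 1.31) and chromaffin minus macrophages by 1.03 (0.75 to 1.30). Mean log2 changes were -0.12 for endothelium, -0.18 for macrophages and -1.02 for adipocytes, but 0.55 for capsule and stroma and 0.24 for Schwann and glial cells. A smaller cortex could also hold fewer vessels and macrophages, so these differences cannot decide on its share. A larger share of chromaffin RNA could not be tested, because the mean change of 0.85 is the pattern itself. More chromaffin cells, a smaller cortex with fewer vessels and macrophages, and higher expression per chromaffin cell stay open, since no cell counts were used here.

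The 4 X-zone markers, none of them in another list, fell by between 0.62 and 4.07. Dilution of cortical RNA by other cells is argued against, because the X-zone mean fell by 2.31 more than the steroid synthesis mean, a difference of -2.31 (95% interval -2.79 to -1.83, two-sided exact permutation p = 0.0286). Strain variants carried along with the floxed allele and lying in or beside the markers themselves are argued against as well. Of the 4 markers, 0 lie among the 100 nearest named genes on either side of Ezh2 in GRCm38.p6. Linked variants that act on distant genes, and variants elsewhere in the mixed background, were not tested. That window held 17 called genes of 200, and 54.0% of the 17404 autosomal windows of this size held at least as many. Akr1d1, among the largest falls, lies on chromosome 6 as Ezh2 does, but outside that window. A linked variant in or beside Akr1d1 was therefore not tested. A loss of X-zone cells could not be judged from the 3.45 log2 units that the changes span, because it is not known here whether other cells express these genes, so fewer cells and lower expression per cell both stay open, as does genotype as the cause.

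Of the 35 splits of the 7 arrays into 3 and 4, only the real one gave as many higher genes (1140 against at most 0 in another). The same held for lower genes (788 against at most 0), 1 split of 35 each, the smallest share that 35 splits can give. A difference between the groups also enters the residuals of the other splits and lowers their counts. The counts thus go against chance but do not exclude it. Other splits reached 3305 genes at an unadjusted p under 0.05, against 5063. For lists it was also 1 split of 35, with 13 lists against at most 12, but the margin is 1 list, and 5 other splits called at least 9 lists, so the number of lists called is no strong evidence against chance.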

How the results depend on the processing

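The adipocyte covariate was chosen after the data were seen. Of 1140 higher and 788 lower genes, leaving out each array in turn gave 594 to 945 higher and 322 to 654 lower genes, and 10 to 14 lists called. Fewer arrays were fitted there, and 0 of the 1928 called genes were called with the opposite sign. A minimum of 1.5-fold left 566 and 236 by construction. With arrays centred on their medians 1329 genes were lower; the centring shifted the median of all genes by -0.05. With the adipocyte list mean as a covariate 583 genes were higher and 364 lower, 881 of them shared with the 1928, and the adipocyte list itself had a median of 0.21; the cause was not tested. With estimated correlations 0 lists were called.

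The replicate numbers did not pair the samples, since deviations of same-numbered arrays correlated at 0.07, -0.08 and -0.11. With the number as a block, limma called 523 higher and 286 lower genes, 739 of them shared with the 1928, Chil3 had an adjusted p of 0.0877, and the macrophage and Schwann lists were not called.

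The chromaffin list mean shares 97.8% of its variance with the group, so as a covariate it leaves little to test and the median SE rose from 0.0703 to 0.450. It left limma with 0 higher and 0 lower genes (1564 at an unadjusted p under 0.05). Camera called 10 lists there, but not the X-zone list (median -0.57, adjusted p = 0.508). Called by camera there but not in the main fit were the glomerulosa (adjusted p = 0.000669), endothelium (0.000417), Wnt target (0.0115), lymphocyte (0.0191) and fasciculata (0.0341) lists. Of the 1928 called genes, 712 had the opposite sign there, among them St8sia5 (-0.52), Tmem130 (-0.83) and Akr1c18 (0.84). Ezh2, not called, also changed sign (0.90). So did the medians of the proliferation (0.22), chromaffin (-0.16), endothelium (0.82) and adipocyte (2.28) lists. The medians of the CDK inhibitor (-0.31), PRC2 (0.47) and Hox (0.003) lists changed sign as well.

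Ezh2 was not called under any setting. Under the filter on low values, the probe set rules, the variance prior, the repeated quantile normalization and the array weights, the counts stayed within 1.5 times. Signal over background was not measured here, which limits what can be said of genes at low levels.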

Other observations

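The test of levels near the floor was chosen after the result was seen, and the test of WT levels was fixed before. The genes of the next 2 paragraphs were chosen after their values were seen.

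The inducible heat shock genes Hspa1b and Hspa1a were lower in KO by limma, with log2 changes of -2.35 (SE 0.24, adjusted p = 0.0032) and -1.92 (SE 0.12, adjusted p = 0.0011). These genes are near-identical copies, so their signals cannot be fully separated. The co-chaperone Hsph1 fell by 0.91 (adjusted p = 0.0102), while Hspa8, Dnajb1 and Hsp90aa1 had log2 changes of -0.21, -0.25 and -0.11 that were not called. Egr1 and Fos changed the other way, by 1.42 and 1.22. The cholesterol exporter Abca1 fell by 1.64 (SE 0.12) and the apolipoprotein Apoc1 by 1.79 (SE 0.14). Among neuronal genes outside the chromaffin list, Snap25 rose by 1.33 (SE 0.11) and Stmn2 by 1.32 (SE 0.20).

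The Hox genes lie in 4 clusters. In cluster B, 9 of 10 measured genes lay below 0, 4 of them called lower, with a median log2 change of -0.37. Clusters A, C and D had medians of -0.06, 0.06 and 0.08, with 0 of 9, 1 of 9 and 0 of 8 genes called. The difference between clusters was not tested.

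Loss of a repressor would be predicted to raise genes that are low in WT. Called higher genes had a median WT level of 6.51 and called lower genes one of 8.18, a difference of -1.67 (permutation p = 1e-05, the smallest that 100000 resamples can give). Grouping genes by the sign of their change lowers the WT level of the higher group by itself, so this value decides nothing. On the mean level over both groups, chosen after the result was seen, the difference was -1.07. Among genes with a mean level between 6 and 11 (863 higher and 700 lower) it was -0.78 (permutation p = 1e-05 each, the smallest possible). This range still holds genes of low WT level that rise, such as Ibsp (4.97 in WT and 9.01 in KO). It therefore cannot decide on the floor, where genes can rise and not fall. Genes are not independent, and the floor, release from repression and a changed share of cell types all stay open.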
